A study of Homo sapiens with 6 samples.

How the data were processed

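The material was 6 fresh frozen sections of normal skin, 10 µm thick, from 2 donors, with the donor, the set and the replicate number taken from the sample titles. Per the labels' protocols, sections on Visium slides were permeabilised for 14 min before capture and reverse transcription. The deposited files hold raw UMI counts per gene and spot, for spots under tissue, with their array positions; per the submitters' processing notes, cutadapt, Space Ranger 1.0.0 and the GRCh38 build were used. How many section replicates of a donor came from separate pieces of skin is not given in the sources used here, so the spread between sections of a donor may be technical.

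From the 33538 gene entries, 92 sex-linked ones were left out and counts of entries sharing a symbol were summed, which left 33422 symbols. Zones were defined in each section from 3 sets of markers and 2 fixed gene lists: KRT1 and KRT10 for epidermis, KRT5 and KRT14 for adnexal keratinocytes, sweat gland anchors (DCD, SCGB2A2, SCGB1D2, MUCL1, PIP, AQP5, KRT7, KRT8, KRT18 and KRT19), and the sebaceous and hair follicle lists. The background of a marker class in a section was the median, over spots, of the mean UMIs of a spot and its neighbours. A spot took the class with a signal of at least 5 UMIs and 5 times the background. Dermal spots had all 5 class signals below 2 times the background in their neighbourhood, and were placed by distance to the nearest epidermal spot into a border band up to 150 µm, a superficial band to 400 µm, an intermediate band to 800 µm and a deep band beyond. Inner epidermis spots had a neighbour outside the epidermis. Adnexal spots within 200 µm of the epidermis, groups of fewer than 5 connected spots and spots with fewer than 100 UMIs were left out, and a zone needed 10 spots.

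This zone rule is not the one written before the data were examined. The planned rule compared keratin UMIs with those of 4 dermal genes (COL1A1, COL1A2, COL3A1 and DCN) by fixed ratios, and it assigned spots all over the sections to the epidermis. A rule on shares of UMIs followed, and the one used here was the last of 3. It was chosen after viewing maps of the markers, maps of the earlier rules and a clustering of the spots with its leading genes, before any test between zones. The sebaceous and hair comparisons came with it. Results for marker genes, and for the sebaceous and hair follicle lists in their own zones, hold by construction.

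UMI counts were summed per donor and zone, giving 18 libraries in 9 zones, and tested with edgeR 4.0.16 (quasi-likelihood test, TMM scaling, filterByExpr by zone, donor as a block, 12608 genes, 8 residual degrees of freedom) at a Benjamini-Hochberg adjusted p of 0.05. A lone library per donor and zone means that all zones share one estimate of the spread. The SE of a fold change was its absolute value over the square root of the test's F statistic. It thus rests on that shared spread and not on the spread between the donors in that comparison alone. Gene lists, 40 fixed before the data were examined and 39 of them measured, were tested with camera of limma 3.58.1 at its preset correlation of 0.01 and with an estimated correlation, and with fry, adjusted over the lists of a comparison. Named genes had an adjusted p under 0.05, at least 50 CPM on the higher side in both donors and the same sign in every section with at least 10 spots on both sides; the 12 largest changes each way were eligible, and list members were named where a list is described. Marker genes, clone names, antibody and T cell receptor variable segments and genes with common deletions or alleles were not named. Gene families with near-identical copies, such as SPRR2, KRTAP, NBPF, HBA1 with HBA2, and LGALS7 with LGALS7B, are uncertain, since their UMIs may be shared.

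Moran's I was taken over the 6 nearest spots on log2(CPM + 100), for genes seen in at least 5% of the spots of every section, with the 15 highest named. Section profiles were compared on log2(CPM + 1). Donors were compared in dermal spots for genes of at least 100 CPM, with a gap of at least 2 times between the lowest section of one and the highest of the other and the 8 largest each way named. Alternatives covered the unit of replication, scaling, test, low count filter, spot minimum, zone rule, depth bounds, sets and each section left out. The test was checked on simulated counts for the 12608 genes, with 100 genes changed by a log2 of 1 and 100 by a log2 of 2 per comparison; with a dispersion of 0.1 it recovered 25% and 80% for epidermis against dermis, 4% and 67% for adnexal spots, 6% and 54% for gland spots, 9% and 55% for sebaceous spots and 5% and 68% for hair spots. The fit's own common dispersion was lower, at 0.0515, and with it the test recovered 36% and 83%, 23% and 85%, 15% and 67%, 16% and 78%, and 17% and 81% in the same order; depth was not varied in these simulations. Other tools were R 4.3.3, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.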

Results

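Messenger RNA was measured in place in 6 sections of normal adult human skin from 2 donors. Each section lay on a Visium slide, an array of barcoded capture spots, so that every unique molecular identifier (UMI) counted belongs to a spot with a known position. A spot covers several cells and is not a replicate; the donors are. The first donor gave 2 replicate sections, and the second donor gave 2 sets of 2 replicate sections. What separates the sets is not given in the sources used here, and no question beyond the description of skin at rest is stated. The sections of the first donor held 2260 and 2692 spots under tissue, with 4754201 and 5062027 UMIs and medians of 669 and 535 UMIs per spot. Set 1 of the second donor held 1869 and 3354 spots, with 7867285 and 13655502 UMIs and medians of 1418 and 1633 per spot. Set 2 held 2333 and 2516 spots, with 4618708 and 5094998 UMIs and medians of 1019 and 1240 per spot. Transcripts of the mitochondrial genome took 4.91% and 5.86% of the UMIs in the first donor, 8.83% in both sections of set 1 and 2.76% and 3.16% in set 2.

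Across genes, the log2 profiles of whole sections correlated with a mean Pearson's r of 0.989 within a set (3 pairs of sections), 0.968 between the sets of the second donor (4 pairs) and 0.969 between donors (8 pairs). Genes are not independent replicates, and these values describe the sections only. With genes of at least 10 CPM (UMIs scaled to an equal total per section) the means were 0.976, 0.874 and 0.888. The last of these averages pairs that lay apart: r was 0.899 to 0.919 between the first donor and set 1, 0.857 to 0.882 between the first donor and set 2, and 0.867 to 0.884 between the sets. As a check for a library deposited in duplicate, the lowest chi-square per degree of freedom of any pair was 4.54, so each section was counted on its own.

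Spots were sorted into zones by marker UMIs over the background of their own section. Epidermis, led by KRT1 and KRT10 (keratins of differentiating keratinocytes), took 1101 spots, 351 in its outer and 750 in its inner part. Spots led by KRT5 and KRT14, keratins of basal and follicle keratinocytes, away from the epidermis numbered 523 and are called adnexal here. Spots led by sweat gland markers numbered 995, those led by sebaceous gland genes 904 and those led by hair follicle genes 734. Dermal spots had few UMIs of all 5 of these marker classes. They numbered 495 in the superficial, 744 in the intermediate and 4913 in the deep band. The rule counted marker UMIs and not their share of a spot's UMIs. Median UMIs per spot were 693 in dermis, 4270 in epidermis and 2151 in gland spots (means of 6 sections). They were 3448 in sebaceous, 7036.5 in hair and 7914 in adnexal spots. Depth per spot thus differed along with the zone. The 4258 spots with mixed signals entered no comparison. The rule asked for no dermal gene. In replicates 1 and 2 of the first donor, COL1A1, COL1A2, COL3A1 and DCN took 3.73 and 3.74 per 10k UMIs in the intermediate band. They took 6.25 and 2.08 in inner epidermis and 34.2 and 18.2 in the deep band. In each section of the second donor the intermediate band was above inner epidermis. The mixed spots, left out of the comparisons, held more of these genes per 10k UMIs than the intermediate band in every section. They were at 10.9 and 6.735 in the first donor and at 10.5 to 21.0 in the second. They lay above the superficial band in each section of the second donor and below it in the first. Only in replicate 1 of set 2 were they above the deep band. The dermis side of a comparison was the mean of the superficial, intermediate and deep bands with equal weights, whatever their UMIs. In the first donor the superficial, intermediate and deep libraries held 37261, 32138 and 829477 UMIs. The fixed ratios planned for this step placed 5323 of the 15024 spots (35.4%) in the outer epidermis and 4465 (29.7%) in the gland zone. They were replaced after maps of the markers and a clustering of the spots had been viewed, and before any test between zones was run; the gene counts under the planned zones stand beside each comparison that has them.

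**Figure D1:**
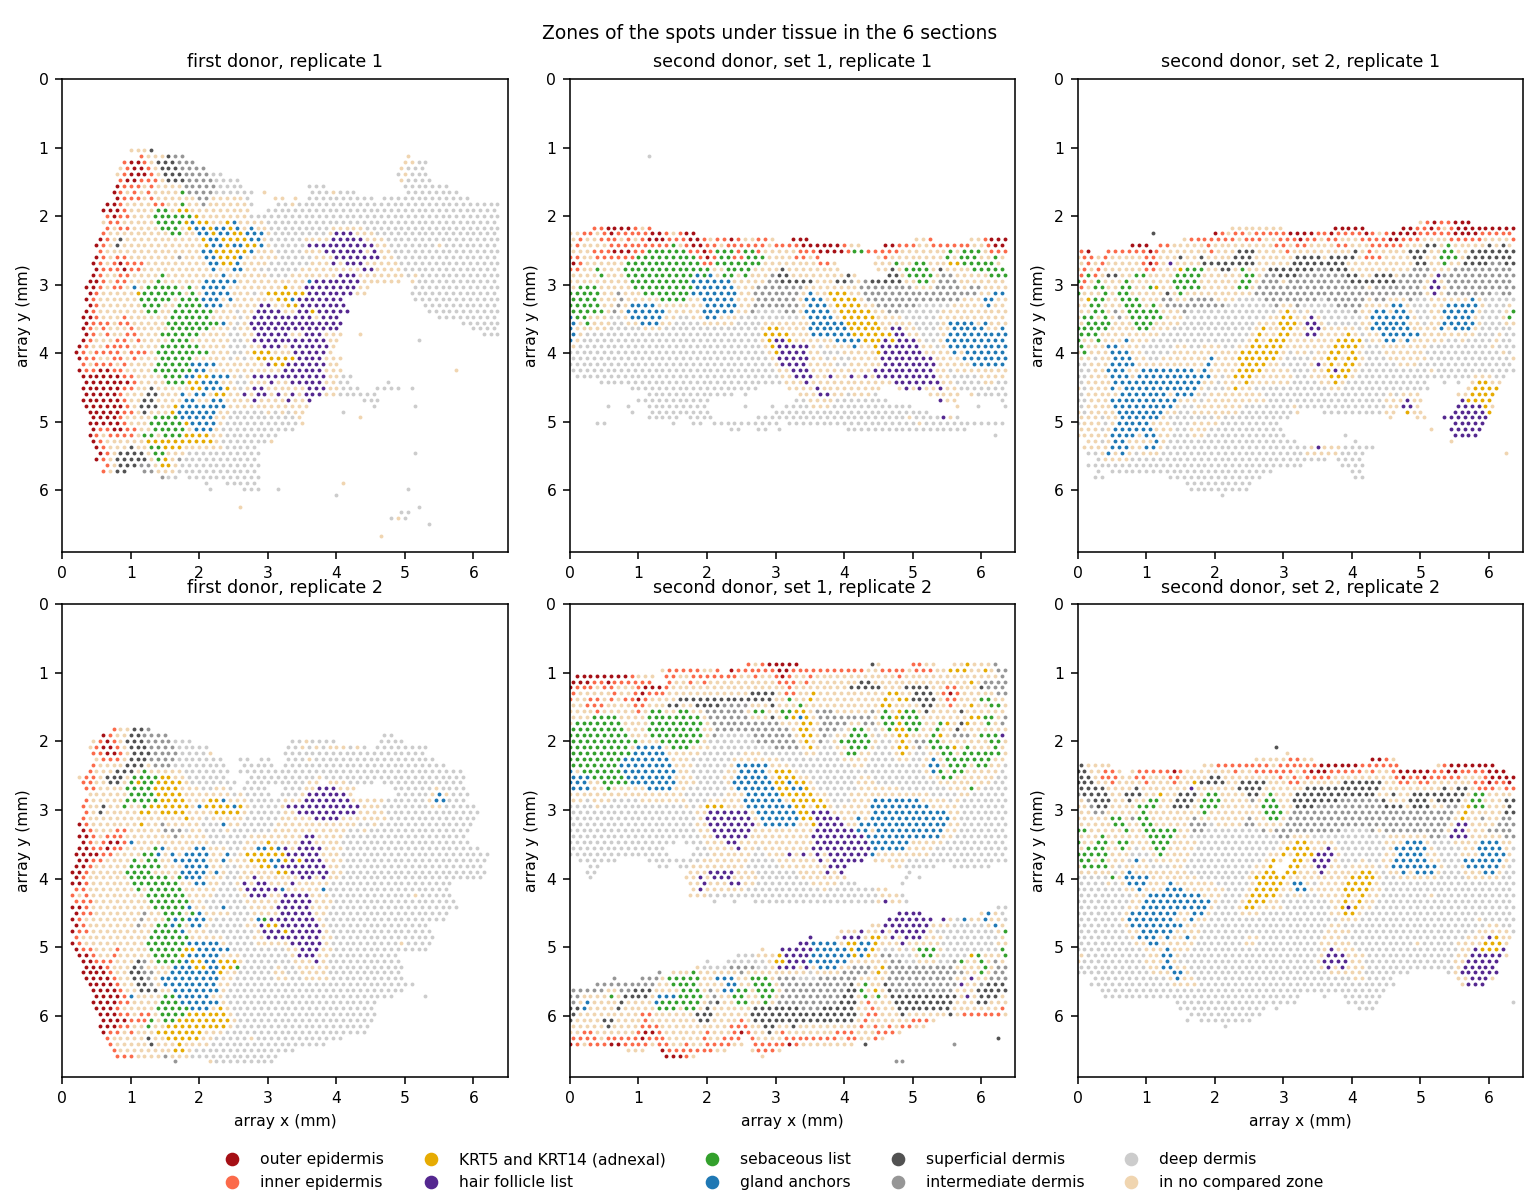
Zone of each spot under tissue in the 6 sections; axes give the position on the array in mm, and colours give the zone. Deep dermal spots made up 33.1% ± 8.65 of the spots of a section and gland spots 6.65% ± 1.74 (mean ± SD, n = 6 sections).

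KRT1 and KRT10 were also counted far from the epidermis. Together they stood at 38221 ± 16289 CPM in epidermal spots (SD, n = 6 sections), 11596 ± 6356 CPM in spots 150 to 400 µm away and 4505 ± 2923 CPM beyond 1600 µm, where 86.1% of spots had a UMI of either gene. The spots counted by distance took in mixed as well as dermal spots. Gland, sebaceous, hair and adnexal spots, isolated epidermal spots and spots with few UMIs were left out of them. The KRT1 and KRT10 UMIs were not subtracted from the levels of any zone.

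**Figure D2:**
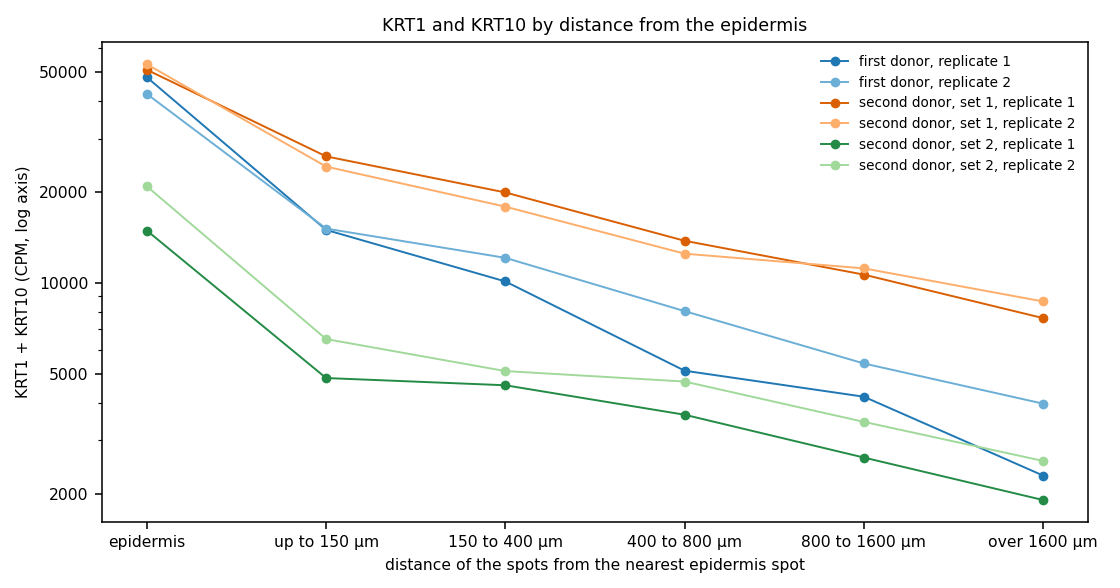
KRT1 and KRT10 together (CPM, log axis) by distance of the spots from the nearest epidermal spot (µm); each line is a section. The mean went from 38221 CPM in epidermal spots to 4505 CPM beyond 1600 µm.

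Epidermis was set against dermis to ask which genes separate the 2 layers of the skin. Among the 12 genes the naming rule gave as most raised in epidermis, S100A8, a subunit of calprotectin, was higher by a log2 fold change of 3.11 ± 0.25 (SE; n = 2 donors, as for all fold changes here), SPRR2B, a precursor of the cornified envelope, by 3.03 ± 0.24, and ARG1, the arginase of the urea cycle, by 2.99 ± 0.24. KRT2, a keratin of the upper spinous layer, rose by 2.93 ± 0.26, and SLURP1, a secreted keratinocyte protein, by 2.87 ± 0.22. In the other direction CCDC80, a matrix protein, stood at −3.69 ± 0.29, the transcription factor EBF1 at −3.51 ± 0.36, PRRX1, a mesenchymal homeobox gene, at −3.04 ± 0.29 and COL4A1, a chain of type IV collagen, at −2.91 ± 0.36. All genes named in this comparison by their size had the same sign in 6 of 6 sections. In all, edgeR's quasi-likelihood test called 3632 of 12608 genes at a Benjamini-Hochberg adjusted p of 0.05, 2062 higher and 1570 lower in epidermis. DESeq2's Wald test split its calls the other way, with 1531 higher and 1877 lower. The planned zones gave 978 genes (487 higher, 491 lower), of which 673 were shared with the count above and 631 of those had the same sign. Without replicate 2 of set 1 of the second donor 2271 genes passed, and without replicate 2 of the first donor 2357. With set 2 as the only set of the second donor the count was 1361.

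Gene lists fixed in advance moved as follows between epidermis and dermis. All 16 measured genes of the spinous layer list were higher in epidermis, over all genes and adjusted over the list alone, with KRTDAP at 2.88 ± 0.30 and LY6D at 2.83 ± 0.27. Of 28 granular and cornified layer genes 23 rose and 1 fell by both adjustments; FLG, which encodes profilaggrin, was at 2.42 ± 0.27, and the gene that fell, TCHHL1, at −2.84 ± 0.66. Of 15 genes of epidermal lipid synthesis 13 rose and 1 fell by both adjustments, with ALOX12B, a lipoxygenase of the lipid envelope, at 2.23 ± 0.32. Among 13 keratins and alarmins of stressed epidermis 11 rose, and 12 when adjusted over the list alone; S100A9 was at 2.62 ± 0.25 and KRT16 at 1.36 ± 0.34. Adjusted p-values of limma's camera test with its preset correlation were 5.83e-19, 1.39e-15, 1.65e-06 and 8.68e-17 for these 4 lists, and with an estimated correlation the adjusted p was 0.0925, 0.0925, 0.219 and 0.0222. Since epidermal spots were chosen by KRT1 and KRT10, genes that vary with these keratins are favoured by the choice of spots.

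On the dermal side, 16 of 17 fibroblast genes fell in epidermis by both adjustments, with COL6A3 at −2.72 ± 0.28, PDGFRA at −2.45 ± 0.57 and VIM the exception at −0.21 ± 0.36. Of 19 genes of pericytes and smooth muscle 17 fell by both adjustments, including MYH11, a smooth muscle myosin, at −3.75 ± 0.57 and RGS5 at −2.31 ± 0.36. Of 15 endothelial genes 12 fell, or 13 adjusted over the list alone, and 1 rose by both: ACKR1 of venules was at −3.25 ± 0.58 and PECAM1 at −2.44 ± 0.40, while IFI27, which is also induced by interferon, was at 2.40 ± 0.28. The camera test gave adjusted p = 1.39e-15, 6.89e-16 and 3.31e-08 for these lists. With an estimated correlation the adjusted p was 0.0925, 0.0925 and 0.153. Genes of the skin appendages were also lower in epidermis, 19 of 24 hair follicle genes by both adjustments and 14 of 18 sebaceous genes, 16 adjusted over the list alone (camera adjusted p = 1.78e-17 and 6.65e-11, and adjusted p = 0.0925 for each with an estimated correlation). Both lists took part in deciding which spots were epidermal and which dermal, so these tests are not independent of the zones. Hair follicle genes took 2.08% of the UMIs in deep dermis and 1.55% in superficial dermis, against 1.03% in inner and 0.747% in outer epidermis (means of 6 sections). Adnexal spots were at 2.06%, close to deep dermis. Of 8 Langerhans cell genes 6 rose and 1 fell by both adjustments (adjusted p = 0.0368 by camera and 0.153 with an estimated correlation), with CD207, or langerin, at 1.94 ± 0.38. Of 10 melanocyte genes 5 rose and 1 fell, 5 and 2 adjusted over the list alone (camera adjusted p = 0.0653); TYRP1 was at 2.19 ± 0.40. Of 29 nuclear genes of the respiratory chain 24 rose and 1 fell, 26 and 1 adjusted over the list alone, with COX6A1 at 1.34 ± 0.23 and the muscle form COX7A1 at −2.06 ± 0.47. Camera gave adjusted p = 7.45e-09 for that list, and with an estimated correlation the adjusted p was 0.235. Camera passed 27 of 39 lists at its preset correlation and 1 with the correlation estimated. For the Notch pathway list the median fold change was positive and the mean and test negative, and for the cell cycle list the median was negative and the mean positive; neither list is read further here.

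Superficial dermis was set against deep dermis to follow depth within the connective tissue. Each of the genes past the test was lower near the surface. ADAMTS4, a protease that cleaves aggrecan, was at −3.22 ± 0.55 (30.1 against 199 CPM; adjusted p = 0.0331), IGFBP5, which binds insulin-like growth factors, at −2.76 ± 0.48 (adjusted p = 0.0331) and AKAP12, a kinase scaffold, at −2.75 ± 0.50 (adjusted p = 0.0351). C11orf96 was at −2.56 ± 0.49 (adjusted p = 0.0431), the apolipoprotein APOD at −2.47 ± 0.46 (adjusted p = 0.0386) and the protease CTSL at −2.31 ± 0.42 (adjusted p = 0.0351), all with the same sign in 6 of 6 sections. In the superficial band of the first donor C11orf96 and CTSL were at 17.9 CPM and AKAP12 at 35.9, levels that rest on very few UMIs. TNS1, named only to complete the count, was lower in 5 of 6 sections, at −2.40 ± 0.47 (adjusted p = 0.0486). The edgeR test called these 7 genes and no gene higher, against 794 at an unadjusted p under 0.05, and called 0 with the planned zones. In the first donor the superficial band held 82 spots and 37261 UMIs, and on simulated data the same test recovered 6% of genes changed by a log2 of 2 and 0% of those changed by 1 with a dispersion of 0.1, and 27% and 3% with the 0.0515 of the fit. Without set 1 replicate 1 of the second donor no gene passed; without replicate 1 or 2 of the first donor 14 and 12 did, and with set 1 or set 2 as the only set of the second donor 15 and 3. With sums per section and the section as a replicate block, which treats sections of a donor as independent, 166 genes passed.

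No member of most lists passed between superficial and deep dermis over all genes, so their counts rest on the list alone. Adjusted over the list alone, 11 of 17 fibroblast genes were lower near the surface and 0 passed over all genes; SPARC, a collagen-binding glycoprotein, was at −1.98 ± 0.49 and FBN1, or fibrillin, at −2.24 ± 0.65 (camera adjusted p = 1.07e-14, and adjusted p = 0.0698 with an estimated correlation). Of 19 pericyte and smooth muscle genes 8 were lower adjusted over the list alone and 0 over all genes, with ACTA2 at −1.96 ± 0.55 and MCAM at −1.41 ± 0.43. Of 13 adipocyte genes 8 were lower adjusted over the list alone and 0 over all genes, among them PLIN1, which coats lipid droplets, at −3.06 ± 0.90 and FABP4 at −1.96 ± 0.56. The size of that difference varied: the list's share of UMIs in deep and superficial dermis was 0.532% and 0.0941%, and 0.333% and 0.0521%, in the sections of the first donor, but 0.0587% and 0.0564%, and 0.0595% and 0.0549%, in those of set 2. Of 15 genes of inflammatory fibroblasts 1, APOD, fell over all genes and 6 adjusted over the list alone, with C3 at −2.08 ± 0.46. Of 13 keratins and alarmins of stressed epidermis 7 were higher adjusted over the list alone and 0 over all genes, S100A9 at 1.51 ± 0.40. Camera gave these 4 lists adjusted p = 3.50e-11, 4.67e-11, 2.00e-11 and 1.07e-14, and with an estimated correlation the adjusted p was 0.0497 for each. Other epidermal genes moved with the keratins and alarmins: the spinous and the granular and cornified lists were higher near the surface by camera (adjusted p = 2.88e-05 and 6.48e-05, and adjusted p = 0.336 and 0.330 with an estimated correlation), with 0 and 3 genes higher adjusted over the list alone. By distance from the epidermis, with mixed spots counted in, KRT1 and KRT10 stood at 11596 CPM at 150 to 400 µm. They were at 6243 CPM at 800 to 1600 µm and 4505 CPM beyond 1600 µm. None of 13 papillary fibroblast genes passed either adjustment; their median was positive and their mean negative (camera adjusted p = 0.949). The rotation test fry, which asks whether a list moves one way, passed no list (lowest adjusted p = 0.0583).

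Outer epidermis against inner epidermis, a comparison along the differentiating layers, gave 0 genes past edgeR's test, 227 at an unadjusted p under 0.05 and 1 by DESeq2's Wald test. The planned zones gave 3, and sums per section with the section as a replicate block gave 32. Spots lie too far apart to separate the layers fully, and the test recovered 29% of simulated changes of log2 2 here with a dispersion of 0.1, and 74% with the 0.0515 of the fit. Of 28 granular and cornified layer genes 0 passed over all genes, and 11 were higher in the outer part adjusted over the list alone: LOR, the loricrin of the cornified envelope, was at 1.55 ± 0.39, KPRP at 1.85 ± 0.48 and SPRR2G at 1.40 ± 0.27. Camera gave that list adjusted p = 3.74e-23; with an estimated correlation the adjusted p was 0.165, and fry gave 0.690. The list made up 2.83% ± 1.86 of the UMIs in the outer and 1.33% ± 0.542 in the inner epidermis (mean ± SD, n = 6 sections). In the first donor the sections were at 1.18% against 0.949% and 0.854% against 0.769%, and in the second donor at 2.16% against 1.67% and 5.92% against 2.25% in set 1 and at 3.29% against 1.20% and 3.54% against 1.16% in set 2. For the basal keratinocyte list the median was negative and the mean positive, with camera adjusted p = 0.819.

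Adnexal keratinocyte spots were set against epidermis to compare keratinocytes of 2 places. Among the 12 genes named as most raised on the adnexal side, FGF18, a growth factor, was at 4.99 ± 0.45 (109 against 4.05 CPM), LHX2, a homeobox gene of follicle stem cells, at 4.84 ± 0.39, ANGPTL7 at 4.61 ± 0.41 and the Wnt receptor FZD8 at 3.48 ± 0.35. Among the 12 named as most lowered there, FLG was at −5.33 ± 0.48 (135 against 7314 CPM), the cytokine IL36G at −5.30 ± 0.44, KRT2 at −5.20 ± 0.45 and LOR at −5.03 ± 0.46. Each had the same sign in 6 of 6 sections. The edgeR test called 1930 genes, 1070 higher and 860 lower. The planned zones gave 116, of which 107 were shared with the 1930, all with the same sign. Without replicate 2 of the first donor 1273 genes passed, and with sums per section and the section as a replicate block 3421 did; with set 2 as the only set of the second donor the count was 1230.

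Of 24 hair follicle genes 10 rose in adnexal spots and none fell, and 14 rose adjusted over the list alone. LGR5, a stem cell receptor, was at 3.32 ± 0.32 and SOX9 at 2.48 ± 0.31. The hair follicle list also took part in sorting these spots. Of 15 basement membrane genes 8 rose, 9 adjusted over the list alone, with NID1, or nidogen, at 2.35 ± 0.31. Pericyte and smooth muscle genes rose too, 7 of 19 and 8 adjusted over the list alone. Of 28 granular and cornified genes 20 fell, 22 adjusted over the list alone, and 2 rose by both, CST6 at 2.14 ± 0.40 and TCHHL1, a gene of the inner root sheath family of trichohyalin, at 3.05 ± 0.52. Among 13 keratins and alarmins of stressed epidermis 8 fell by both adjustments and 1 rose, or 2 adjusted over the list alone; KRT17, a follicle keratin, was at 1.20 ± 0.39. Of 15 interferon-induced genes 8 fell, 12 adjusted over the list alone, IFI44 at −3.37 ± 0.69. Of 10 melanocyte genes 5 fell, 7 adjusted over the list alone, MLANA at −2.89 ± 0.55. Camera gave adjusted p = 3.25e-11, 0.000871, 5.15e-08, 3.54e-23, 5.81e-14, 6.99e-07 and 4.29e-05 for these 7 lists in turn. With an estimated correlation the adjusted p was 0.206, 0.135, 0.0992, 0.0707, 0.0202, 0.228 and 0.206.

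Gland spots were set against dermis to describe spots led by sweat gland markers. ZG16B, a secreted lectin, was at 3.72 ± 0.27 (848 against 57.8 CPM), SLC34A2, a phosphate transporter, at 3.74 ± 0.28, ATP6V0A4, a subunit of the proton pump, at 3.45 ± 0.39 and CA6, a secreted carbonic anhydrase, at 3.42 ± 0.30. LTF, or lactoferrin, rose by 3.43 ± 0.29, with 61.8 CPM in gland spots of the first donor and 2669 in those of the second. EBF1 was lower in gland spots at −2.26 ± 0.40, CCDC80 at −1.97 ± 0.34, COL6A3 at −1.93 ± 0.33 and CLDN5, of endothelial junctions, at −1.96 ± 0.41. Also lower were PRKCB at −2.33 ± 0.43 and FLG2 at −2.24 ± 0.36, which with the planned zones were at 3.92 and 1.63 without passing the test (edgeR adjusted p = 0.0865 and 0.0543). Under 2 variants of the planned rule FLG2 passed with the turned sign, at 3.98 and 1.68 (edgeR adjusted p = 0.0260 and 0.00637). The granular and cornified list, which holds FLG2, took 0.8445% of the UMIs in superficial and 0.8443% in intermediate dermis. It took 0.476% in deep dermis and 0.600% ± 0.689 in gland spots (mean, SD for gland spots, n = 6 sections). Each gene named had the same sign in 6 of 6 sections under the zones used here. The edgeR test called 1169 genes, 839 higher and 330 lower; DESeq2's Wald test gave 605 higher and 397 lower. With the planned zones 673 passed, 384 higher and 289 lower, 317 of them shared with the 1169 and 311 of those with the same sign. The count was 519 without replicate 2 of the first donor, 586 and 746 without replicate 1 or 2 of set 1 of the second donor, and 270 with set 2 as the only set of that donor. With sums per section and the section as a replicate block 2663 genes passed.

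Of 23 sweat gland genes other than the markers that chose the spots, 20 rose and none fell; adjusted over the list alone 20 rose and 1, LYZ, fell. AZGP1 was at 3.06 ± 0.29, SLC12A2, the chloride cotransporter, at 3.18 ± 0.28 and FOXI1, of ionocytes, at 3.75 ± 0.54 (camera adjusted p = 1.27e-50, and adjusted p = 0.0201 with an estimated correlation). The list took 0.356% and 0.536% of the UMIs in gland spots of the first donor and 1.39% to 2.09% in those of the second. Keratinocyte genes went the other way, with spinous genes at 2.62% and 1.79% in the first donor and 0.549% to 1.17% in the second, and hair follicle genes at 2.20% and 1.91% against 0.383% to 1.31%. Of 29 nuclear respiratory chain genes 22 rose, 28 adjusted over the list alone, and here COX7A1 was higher at 2.33 ± 0.40. Of 13 genes of the mitochondrial genome 9 rose, 10 adjusted over the list alone, MT-CO1 at 1.87 ± 0.29. By share of UMIs, the mitochondrial list was higher in gland spots than in deep dermis in every section of the second donor. In the first donor it was lower in replicate 1 and higher in replicate 2. Fibroblast genes fell, 13 of 17 and 15 adjusted over the list alone, with SFRP2 at −2.86 ± 0.66, as did 7 of 15 endothelial genes, 13 adjusted over the list alone, ACKR1 at −2.73 ± 0.62. Camera gave these 4 lists adjusted p = 1.93e-18, 2.44e-07, 5.96e-16 and 2.49e-11, and with an estimated correlation the adjusted p was 0.183, 0.275, 0.151 and 0.151. The spinous, immediate early and epidermal growth factor ligand lists, among others, differed in sign between median, mean or test and are not read further.

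**Figure D3:**
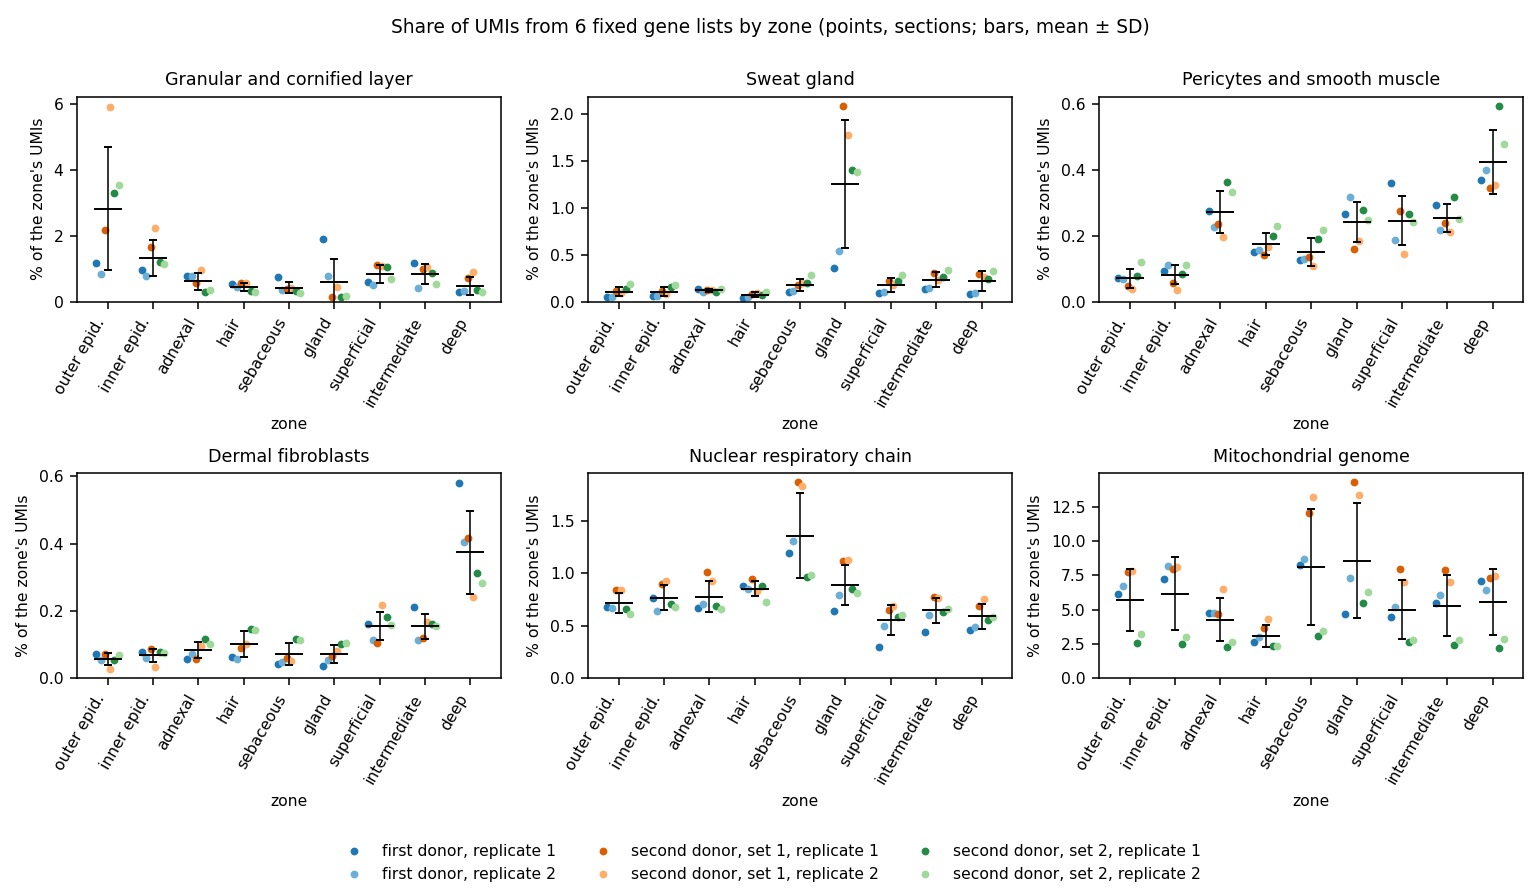
Share of a zone's UMIs (%, y axis) from 6 gene lists in 9 zones (x axis); points are sections, and bars give the mean ± SD over n = 6 sections. Sweat gland genes made up 1.26% ± 0.684 of the UMIs in gland spots and 0.217% ± 0.107 in deep dermis.

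Sebaceous spots against dermis was added after the zones had been seen. All 18 genes of the sebaceous list rose, as the list chose the spots. Among genes outside it, ACOT1, an acyl-CoA thioesterase, was at 5.38 ± 0.33 (186 against 4.17 CPM), HSD3B1, of steroid synthesis, at 4.45 ± 0.30, ALOX15B, a lipoxygenase, at 4.30 ± 0.30 and MOGAT2, of triglyceride synthesis, at 4.42 ± 0.44. HSD11B1, which regenerates cortisol, was at 4.23 ± 0.33. Lower were EBF1 at −2.87 ± 0.41, PRKCB at −2.61 ± 0.44, CCDC80 at −2.53 ± 0.35 and PLA2G2A, a secreted phospholipase, at −2.74 ± 0.79, each with the same sign in 6 of 6 sections. The edgeR test called 3188 genes, 2289 higher and 899 lower, and 937 with set 2 as the only set of the second donor. That donor's sebaceous UMIs came mainly from set 1, with 1615642 and 2204608 in its sections against 163832 and 156957 in those of set 2. In whole sections the sebaceous list took 0.824% of the UMIs in set 1 and 0.154% in set 2, so the sebaceous spots of set 2 stood over a low background.

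Of 29 nuclear respiratory chain genes 28 rose in sebaceous spots by both adjustments, with COX5A at 2.55 ± 0.27. Of 13 genes of the mitochondrial genome 11 rose, 12 adjusted over the list alone, MT-CO1 at 2.12 ± 0.29. Of 15 genes of epidermal lipid synthesis 8 rose by both adjustments, among them ACER1, a ceramidase, at 4.61 ± 0.63 and ELOVL4, which elongates fatty acids, at 2.59 ± 0.29. Fibroblast genes fell, 15 of 17 and all 17 adjusted over the list alone, as did 7 of 18 genes of Wnt signalling, 8 adjusted over the list alone, LEF1 at −1.93 ± 0.36. Camera gave adjusted p = 1.26e-29, 4.90e-07, 0.000995, 1.25e-08 and 0.000679 for these 5 lists. With an estimated correlation the adjusted p was 0.256, 0.340, 0.396, 0.301 and 0.301. In the adipocyte list 4 of 13 genes rose and 1 fell, with DGAT2 at 3.87 ± 0.29, CIDEA at 3.48 ± 0.29 and FABP4 at −1.74 ± 0.44; its median was negative and its mean and test positive (camera adjusted p = 0.0245, and adjusted p = 0.396 with an estimated correlation).

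Hair spots against dermis was likewise added after the zones had been seen, and 17 of 24 hair follicle genes rose and 1 fell, 17 and 2 adjusted over the list alone, on spots that the list chose (adjusted p = 0.0528 with an estimated correlation). Outside it, the metallothionein MT4 was at 4.30 ± 0.32 (498 against 23.6 CPM), LRRC15 at 3.32 ± 0.29, S100A3, a calcium-binding protein of the hair cuticle, at 3.08 ± 0.26 and GPRC5D at 5.15 ± 0.60. KRTAP4-5, a keratin-associated protein with near-identical relatives whose UMIs may be shared, was at 3.08 ± 0.30. Lower in hair spots were PRKCB at −4.77 ± 0.51, IGLC2, an antibody light chain, at −4.43 ± 0.73, SAMHD1 at −4.05 ± 0.43, FLG at −3.80 ± 0.44 and C1QA, a complement gene of macrophages, at −2.88 ± 0.44, each with the same sign in 6 of 6 sections. The dermal level of IGLC2 varied widely, at 300 ± 255 CPM in set 1, 3.55 in set 2 and 225 ± 302 in the first donor (SD, n = 2 sections each). FLG belongs to the granular and cornified list, which took 0.8445% of the UMIs in superficial and 0.8443% in intermediate dermis. It took 0.476% in deep dermis and 0.455% in hair spots (means of 6 sections). Falls of epidermal genes in hair spots are thus relative to dermal bands that held such genes. The edgeR test called 3835 genes, 2323 higher and 1512 lower. The split was 1700 higher and 1686 lower without the 50 most abundant genes in the scaling, and 1778 and 1716 by DESeq2's Wald test. Without replicate 2 of the first donor 2476 genes passed, and with set 2 as the only set of the second donor 1985.

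All 8 genes of MHC class II fell in hair spots by both adjustments, CD74 at −2.52 ± 0.37, and of 12 lymphocyte genes 10 fell, 11 adjusted over the list alone, PTPRC at −3.75 ± 0.59 and IL7R at −4.12 ± 0.70. Of 13 keratins and alarmins of stressed epidermis 10 fell, 11 adjusted over the list alone, PI3 at −2.52 ± 0.37. Of 29 nuclear respiratory chain genes 26 rose and 1 fell by both adjustments, NDUFB1 at 1.82 ± 0.27. Of 18 cell cycle genes 6 rose, 7 adjusted over the list alone, with CCNB1 at 1.33 ± 0.40. Camera gave adjusted p = 1.32e-08, 9.03e-07, 7.59e-09, 4.10e-09 and 0.0270 for these 5 lists, and with an estimated correlation the adjusted p was 0.254, 0.254, 0.134, 0.275 and 0.564. Wnt genes moved both ways: 7 of 18 rose, LEF1 at 2.18 ± 0.27, and 4 fell, SFRP2 at −2.75 ± 0.61, or 8 and 6 adjusted over the list alone (camera adjusted p = 0.637). The granular and cornified list also split, 9 up and 10 down of 28, with a positive median and a negative mean (camera adjusted p = 0.320).

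Spatial pattern was measured without zones by Moran's I, which is 0 for a random layout and nears 1 when neighbouring spots share a level. Of 4328 genes, 485 had a mean I above 0.1 over the 6 sections, and 86 were above 0.1 in every section. Leaving aside the keratin, sweat gland and collagen markers, of which DCD was at 0.632 and KRT1 at 0.419, but not the hair follicle and sebaceous lists that also set zones, the nuclear RNA MALAT1 had the highest mean, 0.637 ± 0.0694 (SD, n = 6 sections), followed by TCHH of the inner root sheath at 0.434 ± 0.157, FLG at 0.400 ± 0.0578 and S100A9 at 0.342 ± 0.113. FADS2, a fatty acid desaturase of sebaceous glands, followed at 0.338, S100A8 at 0.335, FADS1 at 0.312 and the hair keratin KRT85 at 0.309; TCHH, KRT85, FADS1 and FADS2 belong to those lists. By list, the median I was 0.251 for keratins and alarmins of stressed epidermis, 0.241 for the hair follicle, 0.221 for the sebaceous gland and 0.187 for the sweat gland, against 0.0413 for the basement membrane. The 100 genes of highest I in a pair of sections overlapped by 57.3 ± 14.8 genes (SD, 15 pairs). Were all 4328 genes equally likely to rank high, 2.31 would be shared. That figure makes no allowance for the abundance of a gene or the layout of depth, so the overlap that chance gives is not known. The overlap was 76.7 within a set and 47.0 between the sets of the second donor. The first donor shared 64 to 73 genes with the sections of set 1 and 39 to 46 with those of set 2.

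The donors were compared in dermal spots by levels alone, with no test, because 2 donors allow none. Of 2060 genes 114 separated the sections of the donors by a gap of at least a factor of 2, 87 higher in the first donor and 27 in the second. The count was 48 in whole sections, 293 without replicate 2 of the first donor, 283 at 20 CPM or more, 180 with set 1 and 383 with set 2 as the only set of the second donor. If sections were interchangeable, 13.3% of genes would be apart with no demand on the gap; sections of a donor vary together, so the share that chance gives is not known. PLIN1, of lipid droplets, was at 734 ± 187 CPM in the first donor and 21.0 ± 11.5 in the second (SD, n = 2 and 4 sections). HSPA1A, a heat shock gene, was at 842 ± 499 and 40.8 ± 8.23 CPM, G0S2, which restrains lipolysis, at 285 ± 114 and 9.49, and the cytokine IL6 at 102 ± 71.0 and 2.62. HSPA1A belongs to the list of immediate early and heat shock genes, which respond to tissue handling. All members of that list among the 114 genes were higher in the first donor, such as FOS at 1299 ± 143 and 315 ± 83.3 CPM and EGR1 at 1242 ± 284 and 301 ± 111. Whether handling differed between the donors was not tested. PLIN1 and G0S2 belong to the adipocyte list, which took 0.532% and 0.333% of the UMIs in deep dermis of the first donor and 0.0587% to 0.103% in that of the second; ADIPOQ of the same list was at 233 ± 108 and 10.0 CPM. The hemoglobin genes HBA1 and HBA2, near-identical copies, were at 183 ± 127 and 368 ± 184 CPM in the first donor and 1.95 and 13.8 in the second. LGALS7, which shares its sequence with LGALS7B, was at 381 ± 62.1 and 0.819 CPM. HBA1 and LGALS7 had at most 3 counts in any section of the second donor, and LTF at most 3 in any of the first. Higher in the second donor were the acute phase gene SAA1, at 456 ± 93.8 against 19.5 ± 3.69 CPM, S100A9 at 3204 ± 1938 against 337 ± 16.3, PMEL of melanosomes at 122 ± 20.7 against 10.7 and LTF at 307 ± 74.9 against 2.76. LTF, a gene raised in gland spots, belongs to the sweat gland list, as do SAA1 and, also among the named genes, SAA2 and STAC2. That list took 0.243% to 0.331% of the UMIs in deep dermis of the second donor and 0.0787% and 0.0917% in that of the first. The share counts these genes too, so it is not separate from their difference. Antibody genes varied widely among the sections of the second donor, IGKC at 3184 ± 3893 against 34.5 CPM and IGHG1 at 1607 ± 1420 against 45.1.

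**Figure D4:**
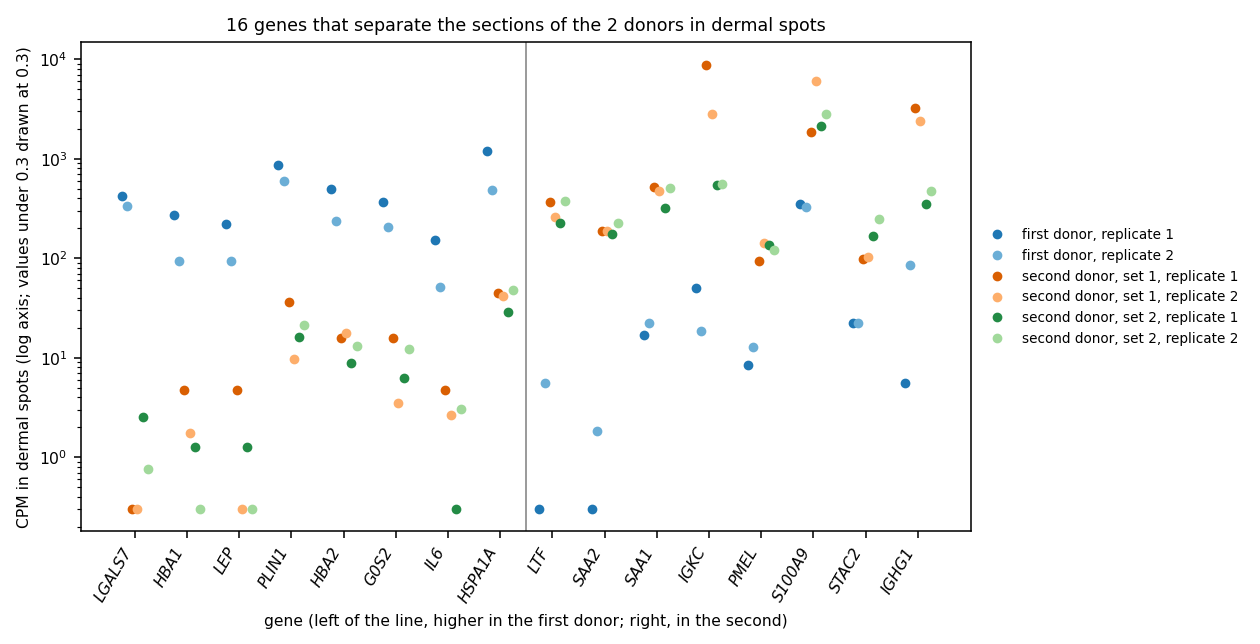
CPM in dermal spots (y axis, log scale) of the 16 genes (x axis) named by the rule for the donors; each point is a section, coloured by donor and set. PLIN1 stood at 734 ± 187 CPM in the first donor and 21.0 ± 11.5 in the second (mean ± SD, n = 2 and 4 sections).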

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

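The comparison of list medians between the donors was looked at only after the zones were set; it is descriptive, and the predictions of the tests on the other 2 patterns were written after the patterns were noticed but before the values of these tests were seen. The check of the makeup of the deep dermal and epidermal spots was chosen after the gap in them was seen, and the KRT1 and KRT10 UMIs per spot near hair after the share of UMIs there. For each list and comparison, the median log2 fold change was taken in every section, and a result is given here where both sections of the first donor lay on one side of 0 and all 4 sections of the second donor on the other. This held for 14 of 273 medians; how many chance gives is not known, since sections of a donor vary together and lists share zones. The differences between donors were not tested. Values are the mean of the first donor's sections, the mean of the second donor's and the first minus the second, all as log2.

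In gland spots against dermis, the first donor was higher for spinous genes (0.91 and −1.23, difference 2.14), granular and cornified genes (0.53 and −1.42, difference 1.95), epidermal lipid genes (0.60 and −1.03, difference 1.63) and Notch genes (0.17 and −0.56, difference 0.73); these differences were not tested, and the gland spots of the first donor held larger shares of spinous genes and smaller shares of sweat gland genes, as the report gives. In epidermis against dermis it was higher for Schwann cell and nerve genes (0.18 and −0.91, difference 1.09), interferon-induced genes (0.29 and −0.39, difference 0.68) and Notch genes (0.23 and −0.46, difference 0.69), again not tested. In outer against inner epidermis it was higher for basal keratinocyte genes (0.09 and −0.56, difference 0.65), Schwann cell and nerve genes (0.29 and −0.75, difference 1.04) and MHC class II genes (0.67 and −0.45, difference 1.12), not tested. In hair spots epidermal lipid genes differed by 0.53 (0.26 and −0.27). The first donor was lower for TGF-beta and BMP genes in adnexal spots (−0.25 and 0.54, difference −0.79), and in superficial against deep dermis for basal keratinocyte genes (−0.22 and 0.23, difference −0.45) and epidermal lipid genes (−0.34 and 0.46, difference −0.80), none of them tested.

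In whole sections, set 2 of the second donor stood apart both from set 1 of the same donor and from the first donor, while set 1 lay closer to the first donor. On genes of at least 10 CPM with a pseudocount of 10 CPM, Pearson's r across genes was 0.981 within a set, 0.891 across the sets and 0.907 on average across donors, a gap of 0.0901 within the second donor. In deep dermal spots r was 0.855 across the sets and 0.820 on average across donors, and in epidermal spots 0.880 and 0.875. Within these zones mean r was no higher across donors than across the sets. The mean across donors pools pairs with set 1 and with set 2 (SD 0.0465 in deep dermal and 0.0229 in epidermal spots, 8 pairs). These spots were not thinned to equal depth, so no order of donors and sets is read from them. The tables argue against depth and a few abundant genes as the whole cause, which required the gap to fall below 50% of its size: with all sections thinned to 4618708 UMIs it was 99.8%, and without the 50 most abundant genes and the mitochondrial ones it was 103%. A different makeup of skin structures stays open: the gap was 93.9% in deep dermal spots alone and 85.5% in epidermal spots alone, but the cell type and layer lists differed between the sets there by a median log2 of 0.47 and 0.43, against 0.50 in whole sections, so neither restriction removed the difference in makeup. A library batch or another place of sampling also stays open and cannot be told apart from the set, whose meaning is not given in the sources used here, and no biological explanation was tested.

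KRT1 and KRT10 were counted far from the epidermis, as the report's levels by distance show. If their RNA had spread from the epidermis, spinous and granular genes should keep in spots beyond 800 µm the ratio to KRT1 and KRT10 that they have in the epidermis; the median log2 ratio of ratios was 1.35 on average (0.62 to 2.47 over 6 sections), above 0 in all and above 1 in 4 of them. This test leaves spread RNA open, because epidermal spots were chosen by KRT1 and KRT10 themselves, which lowers the ratio there. Hair follicle keratinocytes beside these spots also stay open as the source: the share of UMIs from KRT1 and KRT10 within 300 µm of hair and adnexal spots was 0.826 ± 0.168 times (SD, n = 6 sections; 0.644 to 1.07) that beyond 600 µm, below the limit set in advance, but a share falls where follicles add other RNA, and UMIs of the 2 genes per spot were 1.28 ± 0.307 times (0.764 to 1.59), above 1 in 5 of 6 sections, where all UMIs per spot were 1.19 to 2.06 times. No biological explanation was tested beyond that one.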

How the results depend on the processing

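The zone rule used for the values reported, its variants (marker fold, dermal limit, shares of UMIs, adnexal spots beside the epidermis) and the sebaceous and hair comparisons were chosen only after the data were seen; the other alternatives were fixed before the data were examined. Of 3708 values of named genes under these alternatives, 3545 stayed the same, 130 no longer passed the test, 19 moved and 14 reversed. For superficial against deep dermis 46 values no longer passed and 122 stayed, against 1 and 574 for hair spots. Genes with a test had been named for large changes of the same sign in every section, which favours staying the same when a section is left out. Values with a test stayed the same if they passed in the same direction. Values with no test could only stay, move or reverse. Among these, 8 values of Moran's I moved by at least their SD over sections and 153 stayed. Of the log2 ratios of donor means 11 moved by at least 1 and 133 stayed. Counts of genes past the test changed by more than 1.5 times as follows, and the cause was not tested. Smaller zones or fewer sections also leave fewer UMIs, and the effect of that was not tested either. With sums per section and the section as a replicate block, which counts sections of a donor as independent, 166 genes passed for superficial against deep dermis, 32 for outer against inner epidermis, 3421 for adnexal spots and 2663 for gland spots. For superficial against deep dermis the count was 4 with DESeq2 size factors, 19 with DESeq2's Wald test, 111 with no filter on low counts, 15 with only the compared zones in the model, 20 with a marker fold of 3, 1 with a fold of 10 and 14 with dermal spots below 1.5 times background. For outer against inner epidermis it was 1 with the Wald test, 4 with no filter and 74 with only the compared zones. Gland spots gave 711 with only the compared zones and 746 with dermal spots below 1.5 times background. Zones by share of UMIs gave 1730 genes for epidermis, 55 for superficial dermis, 1268 for adnexal, 477 for gland and 2440.0 for hair spots. Adnexal spots beside the epidermis, when kept, gave 1140.

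Under the planned zones the counts were 978 for epidermis, 0 for superficial dermis, 3 for outer epidermis, 116 for adnexal and 673 for gland spots. With keratin UMIs above 0.5 times the dermal ones they were 229, no value for superficial dermis, 128, 174 and 366. Above 8 times they were 906, 2, 1, 159 and 283. With KRT1 and KRT10 at 10% of the keratin UMIs they were 2381, 2, 252 and 797 for the first 4, and at 50% they were 355, 0, 20, 50 and 395. Reversals were confined to these planned-zone settings, and 2 of the 14 passed edgeR's test with their turned sign, both of FLG2, at 0.5 times (adjusted p = 0.0260) and at 10% (adjusted p = 0.00637, the lowest of a range up to 0.985). In the order of the planned rule, 0.5 times, 8 times, 10% and 50%, PRKCB in gland spots was at 3.92, 2.05, 1.39, 1.17 and 1.14 and FLG2 at 1.63, 3.98, 1.30, 1.68 and 1.32. SAMHD1 was at 0.0889 at 8 times, FYB1 at 0.72 at 8 times and 0.25 at 50%, and SERPINA12 in adnexal spots at 1.59 at 0.5 times.

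With set 1 as the only set of the second donor 15 genes passed for superficial dermis. With set 2 alone the counts were 1361 for epidermis, 3 for superficial dermis, 1230 for adnexal, 270 for gland, 937 for sebaceous and 1985 for hair spots. Gene lists past camera numbered 27, 23, 6, 16, 26, 24 and 26 for epidermis, superficial dermis, outer epidermis, adnexal, gland, sebaceous and hair spots, and 1, 6, 0, 1, 1, 1 and 0 with the correlation estimated. Section agreement was 0.976 within a set, 0.874 across sets and 0.888 across donors for genes of at least 10 CPM, and 0.991, 0.957 and 0.963 with a pseudocount of 10 CPM. Genes apart between the donors numbered 48 in whole sections, 283 at 20 CPM or more, 180 with set 1 alone and 383 with set 2 alone.

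Leaving out each section in turn gave 2271 to 3201 genes for epidermis, lowest without set 1 replicate 2 of the second donor and 2357 without replicate 2 of the first. It gave 0 to 14 for superficial dermis, 0 to 0 for outer epidermis, 1273 to 1865 for adnexal, 519 to 1145 for gland, 2178 to 3001 for sebaceous and 2476 to 3538 for hair spots, and 115 to 293 between donors, highest without replicate 2 of the first donor. The lists past camera ranged from 25 to 28, 23 to 24, 3 to 9, 16 to 18, 22 to 26, 20 to 25 and 21 to 25 in the order above, with 3 for outer epidermis without replicate 2 of the first donor. The overlap of the 100 most patterned genes ranged from 54.2 to 60.9.

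Scaling alone moved the median log2 fold change of all genes by more than 0.1 for hair spots, from 0.21 to 0.08 without the 50 most abundant genes. DESeq2's Wald test, which changes the test and the spread along with the scaling, moved it from 0.15 to 0.03 for epidermis, from 0.05 to −0.05 for sebaceous spots and to 0.09 for hair spots; with DESeq2's size factors alone it was 0.05, −0.02 and 0.12.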

Other observations

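The values in this part were looked up after the results were seen, and differences in them were not tested unless a test is named. Respiratory chain genes of the nucleus were spread unevenly over the zones: they made up 1.36% ± 0.403 of the UMIs in sebaceous spots (mean ± SD, n = 6 sections), 0.889% in gland spots, 0.850% ± 0.0718 in hair spots and 0.588% ± 0.115 in deep dermis. Transcripts of the mitochondrial genome made up 8.57% ± 4.18 in gland spots, 8.13% ± 4.21 in sebaceous spots, 6.17% in inner epidermis, 5.56% in deep dermis and 3.06% ± 0.790 in hair spots. Gland spots were above sebaceous spots in the 4 sections of the second donor and below them in the first, at 4.70% and 7.28% against 8.28% and 8.70%. Lymphocyte genes made up 0.257% of the UMIs in deep dermis, with an SD of 0.420 that exceeded the mean, 0.151% in superficial dermis and 0.0108% in hair spots. The fitted changes of the list went the other way between superficial and deep dermis, with a median log2 of 0.81, no gene past edgeR's test and camera adjusted p = 0.000112, or adjusted p = 0.155 with an estimated correlation. Melanocyte genes made up 0.0655% ± 0.0391 in hair spots, 0.0538% ± 0.0134 in inner epidermis and 0.0174% in adnexal spots. Adipocyte genes made up 0.323% ± 0.0671 in sebaceous spots, 0.196% ± 0.194 in deep dermis and 0.0638% in superficial dermis.

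Some genes separated the sets of the second donor in dermal spots, named by the size of the gap after their values were seen (n = 2 sections per set). GREM1, a secreted antagonist of bone morphogenetic proteins, was at 28.4 CPM in set 1 and 3112 ± 899 in set 2, and GPR85, an orphan receptor, at 1.68 and 1007 ± 224; the first donor had 6.98 and 11.2 CPM. In set 2 both were counted in every zone: GPR85 and GREM1 were at 1255 and 4135 CPM in intermediate, 1117 and 3212 in superficial and 951 and 2918 in deep dermis, 708 and 1844 in sebaceous spots, 545 and 1443 in gland spots, 234 and 554 in adnexal spots and 142 and 328 in hair spots. GREM1 stood at 2.24 to 3.30 times GPR85 in each of the 9 zones of set 2. Whether these levels are expression by the tissue or arose in the handling of set 2 was not tested. KLF15, a transcription factor of metabolism, was at 14.3 CPM in set 1 and 354 in set 2, and the follicle keratin KRT75 at 184 and 803. Higher in set 1 were LOR at 479 against 23.8 CPM, the hair keratin KRT33B at 706.5 against 56.3, the lipogenic gene THRSP at 207 against 28.1 and the elongation factor EEF1G at 165 against 18.4. In dermal spots 258 genes separated the sets by at least a factor of 2, against 193 between the first donor and set 1 and 395 between the first donor and set 2. In whole sections the order differed, with 307, 115 and 227 for the same 3 pairs, and in epidermal spots the counts were 275, 147 and 307. These counts take in all symbols, markers and clone names included, with no floor of 3 counts, and so differ from the 180 and 383 genes that the rule used between the donors gives for each set alone. If sections were interchangeable, 33.3% of genes would be apart with 2 sections a side and no demand on the gap; sections of a set vary together, so the share that chance gives is not known.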
